A study of Pseudomonas putida KT2440 with 4 samples.

How the data were processed

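RNA was measured in Pseudomonas putida KT2440, a soil bacterium that breaks down glucose through the Entner-Doudoroff pathway. Per the labels' protocols, the wild-type strain was grown at 30 °C with shaking in M9 minimal medium, a salt medium in which the added carbon source is the only one. The source was glucose, fructose or glycerol at 10 mM or succinate at 15 mM. Overnight cultures were washed, diluted into fresh medium and harvested in mid-exponential phase at an optical density of about 0.4. RNA was protected in cold phenol and ethanol, extracted, treated with DNase and depleted of ribosomal RNA, and the libraries were made with an Illumina mRNA kit after fragmentation and sequenced from both ends, per the labels' protocols. No strand-marking step is described there. There was 1 library per carbon source and therefore 4 libraries in all.

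The deposited files gave 1 RPKM value (reads per kilobase of gene length, scaled to the depth of the library) per gene and library, per the file headers. The aligner, the counting tool and the treatment of reads with several matches are not given in the sources used here. Each file listed 5296 genes by their coordinates on the GenBank sequence AE015451.1, and all 5296 lengths were multiples of 3, so the lengths used for RPKM were coding lengths without untranslated regions. Ribosomal and transfer RNA genes were not among them. Multiplied by gene length, 100% of the values in each library were whole multiples of a single step within a tolerance of 0.01, so the reads behind each value were recovered. They came to 9225728 reads for glucose, 8335981 for fructose, 7996947 for glycerol and 8179083 for succinate. The size of the step gave the same totals, so the deposited RPKM values were scaled to the reads in the listed genes. The median gene had 378, 454, 352 and 331 reads in the glucose, fructose, glycerol and succinate libraries. Between 143 and 181 genes had under 10 reads.

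The files do not pair the coordinates with gene names. Names were taken from a table of RefSeq genes of another assembly of the same strain, LBNL_KT2440_1968, whose coordinates are not printed. A gene of the files was paired with a gene of the table where both ends differed by an offset shared by at least 5 genes and by near neighbours, or where the end at the stop codon fitted the offset of the nearest paired gene. In this way 5105 genes (96.4%) were paired, 4042 at both ends and 1063 at the stop end alone, and 191 were not paired. As a check, a mirrored table gave 0 pairs at both ends and tables shifted by 4 other offsets gave at most 2 at the stop end. Only 1276 paired genes carried a symbol. The others are named by the table's locus tag (PYW03_RS) with their neighbours and no function, and unpaired genes by ORF and their start in the files. Where several genes carry a symbol, the tag is added.

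Values were compared as log2(RPKM + 1), with the pseudocount of 1 RPKM understating differences of low genes. Genes with at least 10 RPKM in at least 1 library were counted, which kept 4684 genes. With 1 library per carbon source there are no replicates, so no difference has a replicate check and no test or p-value is given. The text gives values, counts of genes differing at least 2-fold or 4-fold, and genes at least 4-fold above or below each of the other 3 libraries (called library-specific). Folds of single genes are ratios of RPKM with exact 95% intervals (Clopper-Pearson, given the sum of the reads of both libraries). The intervals cover counting error only and treat reads as independent. PCR reads without molecular identifiers are not independent molecules. Whether both reads of a fragment were counted is not known, and if so they are not independent either. The intervals can therefore be too narrow. Because reads were not marked by strand in the sources used here, the 1692 genes that overlap another listed gene can share reads with it, and near-identical copies, such as repeated elements, can as well.

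The comparisons, the alternatives, the 22 gene lists and the rule for naming genes were fixed before the data were examined. Named genes are the 10 highest and 10 lowest log2 ratios of fructose, glycerol and succinate against glucose among genes with at least 50 RPKM in the higher library, the 5 most abundant and 5 most library-specific genes of each library, and list members. The lists had been fixed by locus tags that the table does not hold. Members were therefore found by symbol, with neighbouring genes within 6 rows telling copies apart, and some under the table's own symbol (ptsP and pfkB next to cra for fruB and fruK, exaA for pedE, ctaD for coxA). The nuo, atp, flagellar and ribosomal lists took all genes with such symbols. In this way 211 different genes were found for 19 lists, and 2 list members lay under the expression filter. Many lists were measured only in part, since members without a symbol were not found. Measured were 4 of 6 fixed Entner-Doudoroff entries, 15 of 22 for the tricarboxylic acid cycle, 16 of 28 for aromatic and amino acids and 13 of 18 terminal oxidases. For carbon regulators it was 6 of 11, for the glyoxylate shunt 1 of 2 and for lower glycolysis and gluconeogenesis 9 of 13. Member counts below refer to measured members. No member was found by symbol for the lists of glucose uptake and periplasmic oxidation, C4-dicarboxylate transport and pyoverdine, which were not analysed as lists here. A list is described by its median log2 ratio, its members at least 2-fold higher or lower, and the percentile of its median among 10000 random lists of the same size drawn from the same 10 bins of mean expression. Percentiles describe these libraries, since genes are not replicates. Random lists were drawn from all counted genes, with or without a symbol and without regard to position. Members of several lists, such as the nuo and atp genes, lie side by side and can change together. A small shared shift can therefore give an extreme percentile.

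Runs of at least 4 neighbouring genes differing at least 4-fold in the same direction, with at most 1 other gene between members, were looked for by a rule chosen after the values were seen. The alternatives tried were pseudocounts of 0.1 and 10 RPKM, no filter, a filter on a mean of at least 50 RPKM, scaling each library by its median ratio to the geometric mean of the 4 libraries, scaling to the same total without each library's 20 most abundant genes, and recovered reads scaled to depth with a counting interval that excludes 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The procedure was tested on simulated data over all 5296 genes, with reads drawn at the libraries' totals. Changed genes were drawn from those with a mean of at least 10 RPKM, and reads varied by counting error alone. The recovery given next therefore does not cover lower genes or differences between single cultures. Of 200 genes changed 2.5-fold, between 95.5% and 98.5% were recovered at the 2-fold threshold over the 6 simulated comparisons, and at least 99.5% of genes changed 4.5-fold. In 100 draws of 4 unchanged libraries, counting error alone gave at most 10 genes at 2-fold in any comparison and at most 1 library-specific gene.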

Results

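The series measured messenger RNA of Pseudomonas putida KT2440 growing on 4 carbon sources, with 1 library for each of glucose, fructose, glycerol and succinate. Its title and design text name the question, which is how gene expression differs between growth on sugars, glycerol and an organic acid. Reads in listed genes numbered between 7996947 in the glycerol library and 9225728 in the glucose library. The 20 most abundant genes took 17.7% of the reads for glucose, 15.5% for fructose, 23.8% for glycerol and 20.2% for succinate. Coordinates below are those of the files on AE015451.1, and every named gene is a coding gene. There were no replicates, and the intervals given cover counting error only. Among genes named below, nosP overlapped another listed gene by 101 bp, pedF and PYW03_RS14065 by 46, pqqE by 35, pgl and PYW03_RS05350 by 29, ORF_3057324 and PYW03_RS14030 by 21, gltR by 20 and ORF_4724712 by 14, and other named genes by at most 8, so that reads in these stretches can be shared. The lists of glucose uptake and periplasmic oxidation, C4-dicarboxylate transport and pyoverdine were not analysed as lists here, because no member was found by symbol. Their genes can still be among those given by locus tag. In the order of the fixed locus tags, gtsA to gtsD of the glucose uptake list fall between gltR and hexR. The kgu genes of that list fall beside ptxS. They were not assigned to single genes of the runs described there.

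On fructose, the genes ptsP and pfkB next to cra and a run of genes around exaA were far higher than on glucose, and 6 of 7 genes for pyrroloquinoline quinone, a redox cofactor, and alcohol oxidation were at least 2-fold higher. Genes in 3 runs near gltR, ptxS and dapF, the Entner-Doudoroff genes zwf and pgl, cytochrome bo oxidase genes and the chaperone genes groL and dnaK were lower. Of 4684 genes, 741 were at least 2-fold higher in the fructose library and 207 at least 2-fold lower, and 173 and 63 at 4-fold. The median gene was higher by 0.23 on the log2 scale, and relative to it the list medians given next were lower by that amount, such as -1.93 for heat shock and oxidative stress genes and -0.75 for ribosomal protein genes. Median-ratio scaling moved that median by -0.24 and the split to 511 higher and 304 lower genes, which changed the share of higher genes from 78.2% to 62.7%.

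In the fructose phosphotransferase list, the uptake system that phosphorylates fructose, 2 of 3 measured members were at least 2-fold higher in the fructose library, and the median log2 ratio of 4.83 lay at percentile 99.975 of random lists. The ptsP copy next to cra (PYW03_RS04220, 909491 to 912343) was at 1367 RPKM against 45.6 on glucose, 30.0-fold higher (95% interval 28.3 to 31.8). Its neighbour pfkB (912344 to 913291) was 29.5-fold higher (25.7 to 33.9), while cra itself, the regulator, was at 116 against 80.8 RPKM. The adjacent PYW03_RS04230 was at 740.5 RPKM against 25.6.

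Of the genes for pyrroloquinoline quinone synthesis and alcohol oxidation, 6 of 7 were at least 2-fold higher and the median of 2.49 lay above all 10000 random lists. The alcohol dehydrogenase gene exaA (3061563 to 3063458) was at 6126 RPKM against 5.60, or 1093-fold higher (897 to 1347). The related pedH was 18.5-fold higher (15.5 to 22.3), pqqC 6.48-fold (5.88 to 7.15) and pqqB 5.68-fold (5.18 to 6.23), while pqqF was at 41.1 against 34.3 RPKM. All 10 genes ranked highest lay in 1 run of 22 neighbouring genes from 3048838 to 3073962, each at least 4-fold higher. Among them were pedF at 412-fold (230 to 826), nosP at 218-fold (146 to 341) and PYW03_RS14050, which had 4 reads in the glucose library, at 1044-fold (408 to 3835). PYW03_RS14065, PYW03_RS14030, PYW03_RS14085, PYW03_RS14070, ORF_3057324 and PYW03_RS14040 had log2 ratios from 6.32 to 7.93.

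The 10 genes ranked lowest were led by PYW03_RS17560 (start 3772385), at 5.77 RPKM against 647 on glucose, 112-fold lower (66.7 to 206). Of the others, 6 lay beside ptxS, a regulator of 2-ketogluconate genes, in a run from 3819509 to 3832120: PYW03_RS17775 was 30.1-fold lower (27.0 to 33.6), and PYW03_RS17810, PYW03_RS17770, PYW03_RS17790, PYW03_RS17815 and PYW03_RS17785 were 28.4-, 21.7-, 18.5-, 18.0- and 16.9-fold lower. PYW03_RS17990 was 22.8-fold lower, PYW03_RS06515 18.6-fold and PYW03_RS05330, in the run between gltR and hexR, 18.5-fold.

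The Entner-Doudoroff pathway breaks glucose 6-phosphate down to pyruvate and glyceraldehyde phosphate. Its fixed list also held gap, and eda and glk were not among the measured members. The list median was -0.81 (percentile 3.90), with 2 of 4 measured members at least 2-fold lower. That median lay past 2-fold after median-ratio scaling. Glucose-6-phosphate dehydrogenase zwf next to pgl (PYW03_RS05350) was 2.19-fold lower (2.15 to 2.23) and pgl 3.11-fold lower (3.01 to 3.21), whereas gap was at 2715 against 2259 RPKM and edd at 515 against 729. Among carbon regulators, hexR next to zwf (PYW03_RS05345) was 3.22-fold lower and ptxS 2.11-fold lower, and the other 4 measured members, gltR and hfq among them, differed less than 2-fold. The list median was -0.34 (percentile 7.29). Glycerol genes glpD and glpK were 2.54-fold and 2.63-fold lower, and the glycerol list median was -1.32 (percentile 0.245).

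Heat shock and oxidative stress genes had a median of -1.69, below all 10000 random lists, with 8 of 11 members at least 2-fold lower. The chaperonin gene groL was at 1410 against 6697 RPKM, 4.75-fold lower (4.68 to 4.82), dnaK 4.09-fold lower (4.01 to 4.18) and htpG 4.86-fold lower (4.71 to 5.00). In contrast, rpoS, the sigma factor of stationary phase and general stress, was 3.08-fold higher (3.02 to 3.13). Terminal oxidases, the last enzymes of respiration, went in opposite directions, with 5 members lower, 6 higher and 2 neither. All 5 were cyo genes, from cyoD at 4.89-fold lower (4.38 to 5.46) to cyoE next to cyoD (PYW03_RS04330) at 3.05-fold. The higher members were ctaD at 13.6-fold (12.1 to 15.4), coxB at 7.38-fold (6.71 to 8.13), the ccoN, ccoO and ccoP copies PYW03_RS22335, PYW03_RS22340 and PYW03_RS22350 at 3.70- to 3.81-fold, and cydB at 2.14-fold, which lay under 2-fold after median-ratio scaling and at a pseudocount of 10 RPKM. The list median was 0.33 (percentile 79.7), and past 2-fold at a mean of at least 50 RPKM.

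In the tricarboxylic acid cycle, 3 of 15 genes were at least 2-fold higher and 4 lower, with a median of -0.14 (percentile 23.0). The lower genes were sucC, sucD, the lpdA copy PYW03_RS21980 and the malate:quinone oxidoreductase copy PYW03_RS06525, which was 4.53-fold lower (4.23 to 4.86), and the higher ones acnA, icd and the mqo copy PYW03_RS15300. After median-ratio scaling icd lay under 2-fold and odhB was at least 2-fold lower. Anaplerotic genes had a median of -0.57 (percentile 7.91), with oadA 3.05-fold lower (2.96 to 3.15). Genes for catabolism of aromatic and amino acids had a median of 0.69 (percentile 95.95), and 6 of 16 were at least 2-fold higher, among them benA, benB and benC at under 31 RPKM. Of these 6, benC lay under 2-fold at a pseudocount of 10 RPKM and the catA copy PYW03_RS19545 there and under both other scalings. Of 33 flagellar genes, flgB, flgC, flgD and flgE were at least 2-fold higher, of which flgD and flgE lay under 2-fold after median-ratio scaling, and the list median was 0.26 (percentile 84.0). Ribosomal protein genes had a median of -0.52, below all 10000 random lists, with 3 of 53 at least 2-fold lower, and rplL, rplC, rpsN, rpmD and rpsR as well after median-ratio scaling. The ATP synthase median was -0.54 (percentile 13.7). No member differed 2-fold in lower glycolysis and gluconeogenesis (median 0.07), the pentose phosphate pathway (0.15), NADH dehydrogenase (0.20), polyhydroxyalkanoate metabolism (0.29) or the housekeeping list (-0.18), and the first 3 of these medians turned negative under median-ratio scaling. The single measured glyoxylate shunt member, aceA, had a log2 ratio of 0.58 (percentile 80.1).

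On glycerol, glpD and glpK of glycerol catabolism, the exaA run and aceA of the glyoxylate shunt, which bypasses the decarboxylating steps of the tricarboxylic acid cycle, were higher than on glucose. Runs near gltR, ptxS and dapF, all 4 measured Entner-Doudoroff genes and the chaperone genes groL and dnaK were lower. There were 422 genes at least 2-fold higher in the glycerol library and 263 lower, and 125 and 77 at 4-fold. The median gene differed by 0.02 on the log2 scale, and by 0.13 after scaling to the same total without the most abundant genes, which gave 509 higher and 204 lower genes.

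In the glycerol list, glpD, the glycerol 3-phosphate dehydrogenase gene (1231166 to 1232710), was at 4370 RPKM against 81.3, 53.7-fold higher (50.7 to 57.0). The glycerol kinase gene glpK was 7.24-fold higher (6.96 to 7.53), and the regulator glpR was at 135 against 81.3 RPKM. The list median was 2.85 (percentile 99.99). PYW03_RS05620, next to glpK, was at 1062 against 120 RPKM. The isocitrate lyase gene aceA (4653520 to 4654845) was 10.2-fold higher (9.74 to 10.6), a log2 ratio of 3.34 at percentile 99.5.

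All 10 genes ranked highest were again members of the exaA run. In the glycerol library exaA was at 11134 RPKM, 1987-fold higher than on glucose (1631 to 2448), and took 2.11% of the reads. PYW03_RS14050 was 3712-fold higher (1449 to 13626), pedF 1587-fold (887 to 3180) and nosP 1024-fold (688 to 1599). PYW03_RS14065, PYW03_RS14085, PYW03_RS13995, PYW03_RS14070, PYW03_RS14030 and ORF_3057324 had log2 ratios from 8.40 to 9.80. The list of pyrroloquinoline quinone and alcohol oxidation had a median of 4.11, above all 10000 random lists, with 6 of 7 genes at least 2-fold higher. Of these, pqqC was 19.9-fold higher (18.1 to 21.8), pqqE 11.3-fold (10.5 to 12.2) and pedH 58.2-fold (49.0 to 69.7).

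**Figure D1:**
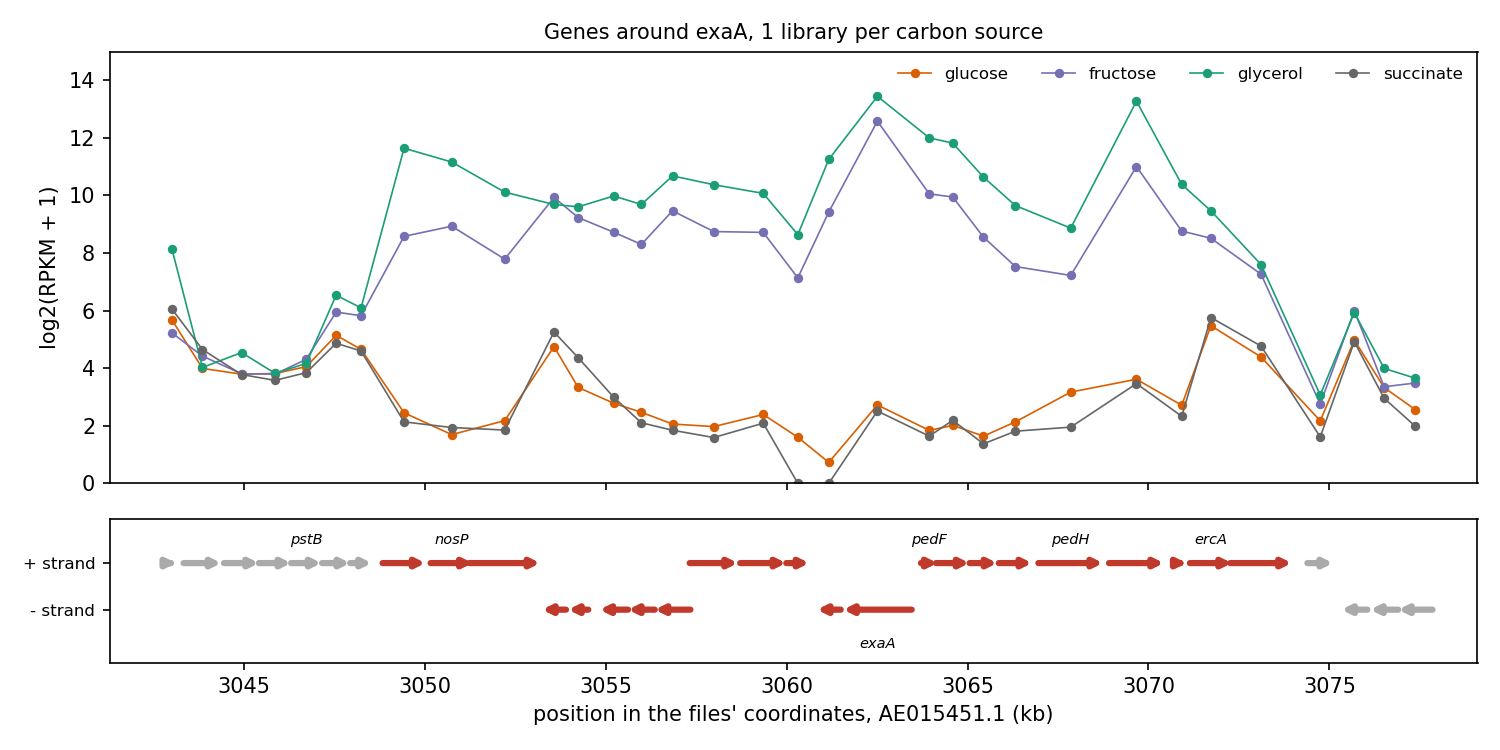
Expression around exaA, as log2(RPKM + 1) of each gene against its position on AE015451.1 in kb for the 4 libraries (upper panel), and the genes by strand, with the run of 22 genes in red and others in grey (lower panel). In the run, exaA stood at 6126 RPKM on fructose and 11134 on glycerol, against 5.60 on glucose and 4.71 on succinate.

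The 10 genes ranked lowest against glucose all lay in 4 runs. Between gltR and hexR, PYW03_RS05320 (1159286 to 1160194) was 105-fold lower (78.5 to 142), PYW03_RS05330 96.8-fold (80.9 to 117), PYW03_RS05325 66.6-fold and PYW03_RS05315 61.1-fold. Beside ptxS, PYW03_RS17790, PYW03_RS17775 and PYW03_RS17785 were 97.8-, 76.5- and 73.5-fold lower. PYW03_RS17560 was 71.7-fold lower, and near dapF (PYW03_RS19935), PYW03_RS19905 and PYW03_RS19890 were 50.9- and 48.0-fold lower. The Entner-Doudoroff list had a median of -2.22 (percentile 0.04), with pgl 5.41-fold lower (5.19 to 5.64), edd 4.71-fold, zwf (PYW03_RS05350) 4.65-fold (4.53 to 4.76) and gap 3.79-fold (3.67 to 3.91). Among carbon regulators, hexR (PYW03_RS05345) was 6.31-fold lower, ptxS 4.83-fold and gltR 3.45-fold, and the median was -1.34 (percentile 0.05).

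Heat shock and oxidative stress genes had a median of -1.16 (percentile 0.01), with 7 of 11 at least 2-fold lower, among them groL at 3.56-fold (3.51 to 3.61), dnaK at 2.65-fold (2.60 to 2.70) and dnaJ, which lay under 2-fold without the most abundant genes in the total, while rpoS was at 3076 against 1671 RPKM. Terminal oxidases again split, with 5 lower and 5 higher of 13 and a median of 0.15 (percentile 85.3), cyoD being 4.68-fold lower and ctaD 5.60-fold higher (4.93 to 6.38). In the tricarboxylic acid cycle (median -0.15, percentile 53.0), sucC, sucD and the mqo copy PYW03_RS06525 were lower and acnA higher, as was the mqo copy PYW03_RS15300 without the most abundant genes. The ATP synthase median was -0.82 (percentile 2.41), with atpG alone at 2-fold, 2.01-fold lower (1.96 to 2.07), and under 2-fold without the most abundant genes. The anaplerotic median was -0.76 (percentile 3.99). The ratio of RPKM of oadA was 2.00-fold lower (1.95 to 2.06), but on log2(RPKM + 1) it lay just under 2-fold. It passed 2-fold after median-ratio scaling and at a pseudocount of 0.1 RPKM. Ribosomal protein genes had a median of -0.49 (percentile 0.275), with no member at 2-fold. In polyhydroxyalkanoate metabolism, the storage polyester of this bacterium, phaG was 3.60-fold higher (3.48 to 3.72) and the median was 0.78 (percentile 98.7). Of the aromatic and amino acid list, 4 of 16 genes, benA, benB, benC and the lpdA copy PYW03_RS23100, were at least 2-fold higher (median 0.21, percentile 63.5), and all 4 lay under 2-fold at a pseudocount of 10 RPKM. Of 33 flagellar genes flgC alone was at least 2-fold higher (median 0.18, percentile 98.3), but not at that pseudocount or after median-ratio scaling. Medians were -0.39 for lower glycolysis and gluconeogenesis, 0.07 for the pentose phosphate pathway, -0.12 for NADH dehydrogenase, -0.08 for housekeeping genes, which turned positive without the most abundant genes in the total, and 0.04 for the fructose list, with no member of these at 2-fold.

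On succinate, fewer genes differed from glucose, and among them the 4 measured Entner-Doudoroff genes and genes of runs near gltR, ptxS and dapF were lower. The gene ranked highest was PYW03_RS06185, and the 10 ranked lowest lay in the runs near gltR and ptxS and in a run from 3865855 to 3869473. There were 154 genes at least 2-fold higher in the succinate library and 156 lower, or 177 and 144 without the most abundant genes in the total, and 17 and 69 at 4-fold. The median gene differed by 0.01.

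All 4 measured Entner-Doudoroff genes, of 6 in the fixed list, were at least 2-fold lower, and their median of -4.28 lay below all 10000 random lists. The lactonase gene pgl (1167055 to 1167783) was at 51.7 RPKM against 2328, 45.1-fold lower (40.3 to 50.6), zwf (PYW03_RS05350) 31.7-fold (29.9 to 33.7), gap 12.0-fold (11.4 to 12.7) and edd 10.3-fold. Between gltR and hexR, PYW03_RS05320 was 152-fold lower (108 to 221), PYW03_RS05325 145-fold (106 to 203), PYW03_RS05315 125-fold (111 to 142) and PYW03_RS05330 102-fold (84.6 to 123). Beside ptxS, PYW03_RS17775 was 113-fold lower (91.4 to 140), PYW03_RS17790 100.0-fold and PYW03_RS17785 86.2-fold. PYW03_RS17995, PYW03_RS17985 and PYW03_RS17990, which lie together from 3867081 to 3869473, were 132-, 103- and 75.2-fold lower. Among carbon regulators, ptxS was 6.66-fold lower, gltR 6.79-fold and hexR (PYW03_RS05345) 3.37-fold, and the median was -0.97 (percentile 0.02).

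The gene ranked highest, PYW03_RS06185 (1363306 to 1364628), was at 1798 RPKM against 27.0, 66.7-fold higher (59.8 to 74.6). PYW03_RS04670 was 12.9-fold higher (11.6 to 14.3), its neighbour PYW03_RS04665 7.26-fold, PYW03_RS07275 7.90-fold and PYW03_RS06755 7.27-fold. Of genes with a symbol, azu, the copper protein azurin, was 6.84-fold higher (6.37 to 7.36), eat 6.80-fold (6.07 to 7.64) and aspA, aspartate ammonia-lyase, 6.10-fold (5.83 to 6.39). ORF_4724712, which has no pair in the name table, was at 10097 against 1776 RPKM, and PYW03_RS14360 was 5.01-fold higher.

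Few measured members of the other lists differed 2-fold on succinate. Of lower glycolysis and gluconeogenesis 9 of 13 fixed entries were measured, and fbp, pckA and pgk were not among them. No member of 11 differed 2-fold among heat shock and oxidative stress genes (median -0.19, percentile 4.07), and groL was at 5857 against 6697 RPKM. The pyrroloquinoline quinone and alcohol oxidation median was -0.20 (percentile 8.51), with exaA at 4.71 against 5.60 RPKM and pedH 2.79-fold lower (1.96 to 4.04), but under 2-fold at a pseudocount of 10 RPKM. Terminal oxidases had a median of -0.33 (percentile 0.235), with cyoE (PYW03_RS04330) 2.11-fold lower. In the anaplerotic list oadA was 5.06-fold lower (4.86 to 5.26; median -0.06, percentile 33.5), and in the tricarboxylic acid cycle the mqo copy PYW03_RS06525 3.59-fold lower (median -0.03, positive without the most abundant genes in the total, percentile 32.2). The glycerol list had glpK 2.87-fold and glpD 3.12-fold lower and glpR 2.38-fold higher (median -1.51, percentile 0.15), aceA was 2.22-fold higher (2.11 to 2.34; percentile 96.4), phaG 2.15-fold lower (list median 0.14, percentile 65.7) and hmgA 2.24-fold higher (list median 0.21, percentile 95.2), but under 2-fold at a pseudocount of 10 RPKM. Ribosomal protein genes had a median of -0.22, below all 10000 random lists, with no member at 2-fold except rpsJ after median-ratio scaling. No member differed 2-fold in lower glycolysis and gluconeogenesis (median 0.07), the pentose phosphate pathway (0.13), NADH dehydrogenase (-0.09), ATP synthase (-0.19), the fructose list (-0.34), the flagellar list (0.06) or the housekeeping list (-0.02, positive without the most abundant genes in the total).

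**Figure D2:**
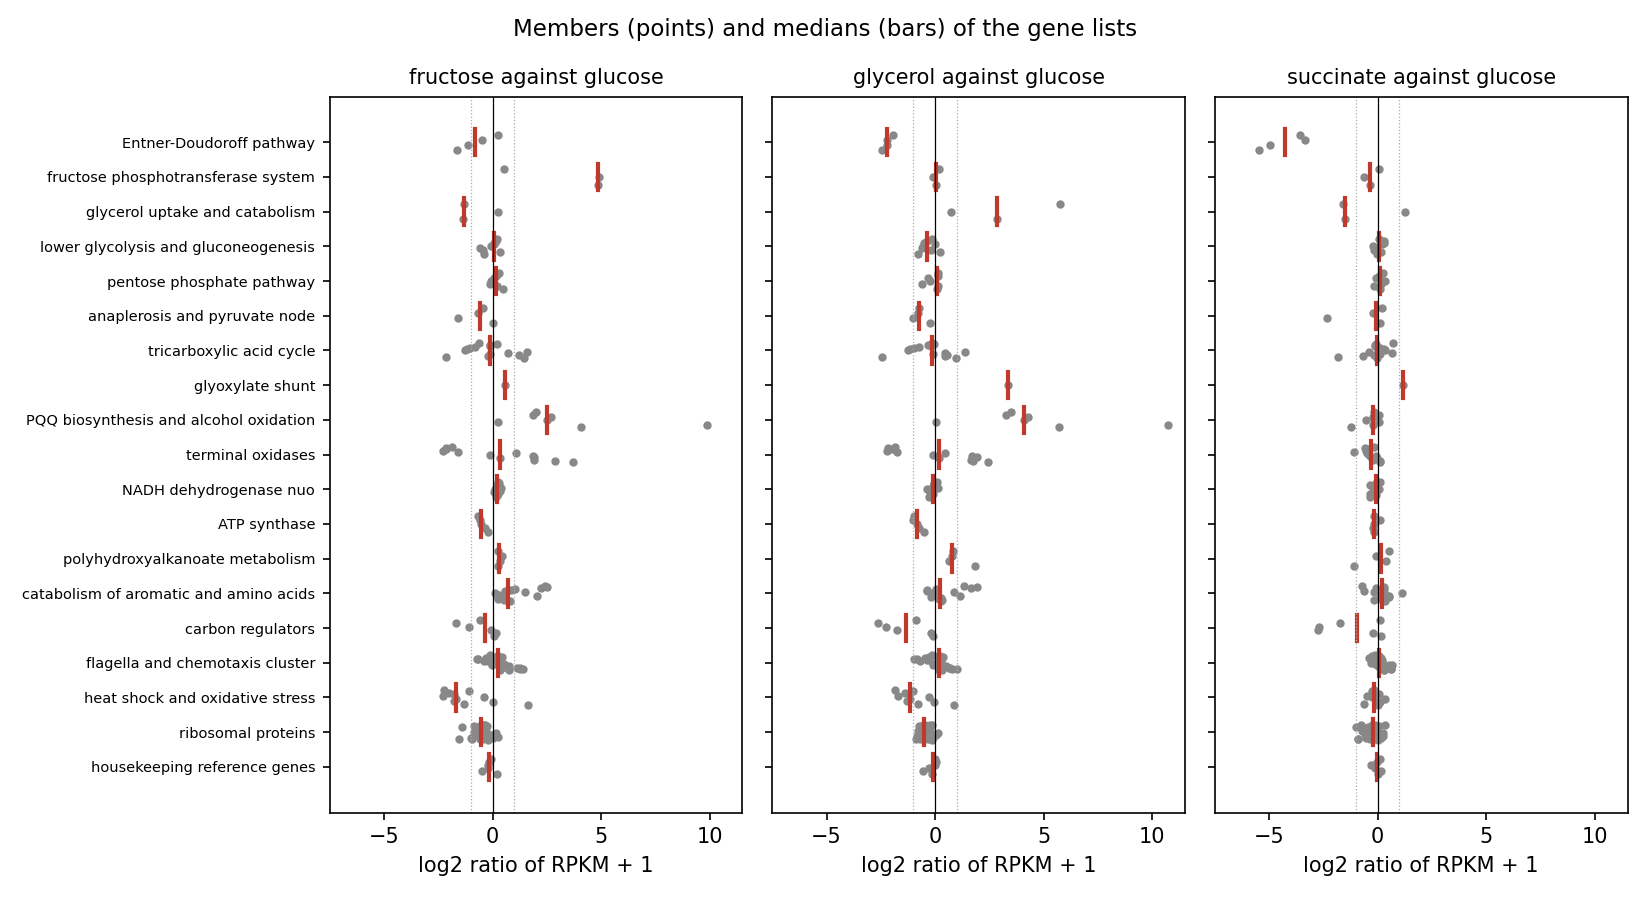
Log2 ratio of RPKM + 1 of each list member (grey points) and list medians (red bars; PQQ, pyrroloquinoline quinone) for fructose, glycerol and succinate against glucose, with dotted lines at 2-fold. The heat shock and oxidative stress median stood at -1.69, -1.16 and -0.19, and the Entner-Doudoroff median at -0.81, -2.22 and -4.28.

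Between the libraries other than glucose, the medians of the Entner-Doudoroff list and of the pyrroloquinoline quinone list were lowest on succinate, and 6 of 11 heat shock and oxidative stress genes were at least 2-fold higher on succinate than on fructose, and 6 of 11 than on glycerol. Between succinate and fructose, 237 genes were at least 2-fold higher on succinate and 859 lower, with an all-gene median of -0.22 that median-ratio scaling moved by 0.22, giving 368 higher and 627 lower genes (21.6% and 37.0% higher). The Entner-Doudoroff median was -3.84, the fructose list median -5.16 and the pyrroloquinoline quinone median -2.88, while heat shock and oxidative stress genes, with a median of 1.67, lay above all 10000 random lists, although rpoS was lower on succinate with a log2 ratio of -1.60 and clpB had a log2 ratio of 0.15. Between succinate and glycerol, 378 genes were higher on succinate and 563 lower. Here the glycerol list had a median of -4.36, the Entner-Doudoroff list -2.21, pyrroloquinoline quinone genes -4.50 and heat shock genes 1.14, with rpoS at -0.86. Between glycerol and fructose, 145 genes were higher on glycerol and 256 lower (36.2% higher, against 52.2% with 176 higher and 161 lower after median-ratio scaling, which moved the all-gene median of -0.25 by 0.23). Scaling without the most abundant genes moved that median by 0.15. The glycerol list median was 4.23, the fructose list median -4.78, the Entner-Doudoroff median -1.41, the pyrroloquinoline quinone median 1.48 and the heat shock median 0.48, with no heat shock member of 11 at 2-fold.

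**Figure D3:**
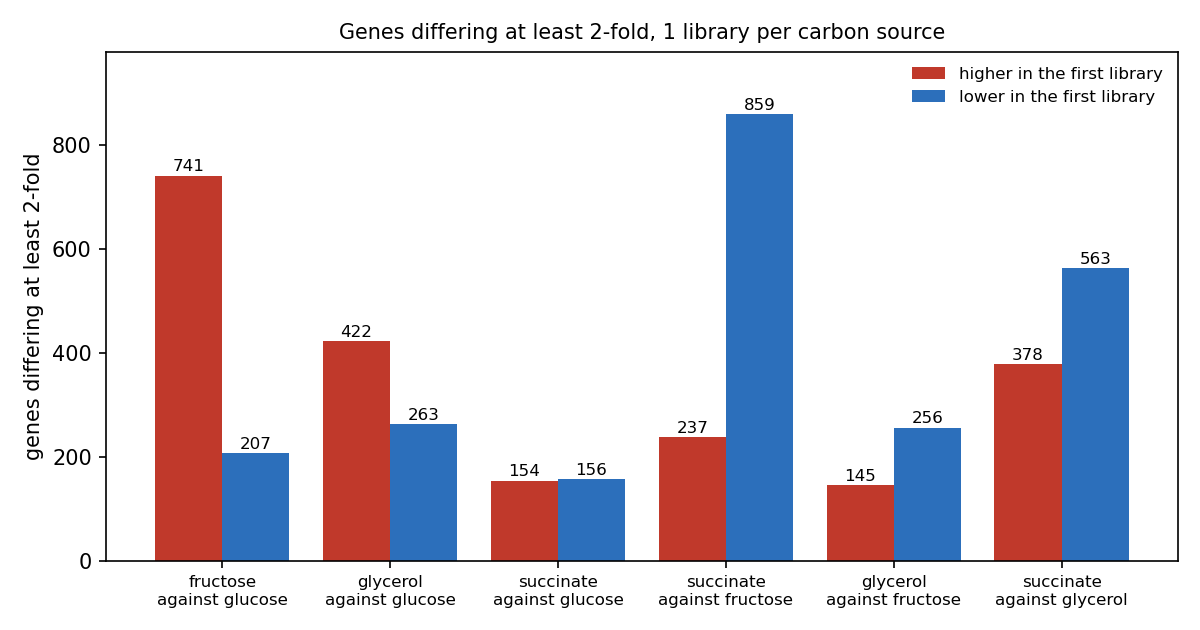
Number of genes at least 2-fold higher (red) or lower (blue) in the first-named library for the 6 comparisons, with 1 library per carbon source. The numbers run from 154 higher and 156 lower genes for succinate against glucose to 237 higher and 859 lower for succinate against fructose.

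Library-specific genes numbered 31 above and 1 below the others for glucose, 13 and 10 for fructose, 17 and 4 for glycerol, and 3 and 8 for succinate. For glucose, PYW03_RS17775 was at 1271 RPKM against at most 42.2 elsewhere, and PYW03_RS17810, PYW03_RS17990, PYW03_RS17770 and PYW03_RS05330 followed with smallest log2 differences from 4.19 to 4.55. The single gene below was azu, at 212 RPKM against at least 1452. For fructose, ptsP (PYW03_RS04220), pfkB and PYW03_RS04230 led, followed by PYW03_RS06755, at 1992 RPKM against at most 280, and PYW03_RS12550, which stood at 15.5 RPKM or less in the other libraries. For glycerol, PYW03_RS16735 stood at 464 RPKM against at most 5.44, glpD at 4370 against at most 81.3 and PYW03_RS16745 at 315 against at most 14.5, PYW03_RS12570 was below the others at 61.2 RPKM against at least 635, and PYW03_RS05620 was above. For succinate, PYW03_RS06185 was above the others, and pgl, ORF_6062911, PYW03_RS17985 and PYW03_RS17995 were below, with pgl at 51.7 RPKM against at least 430.

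**Figure D4:**
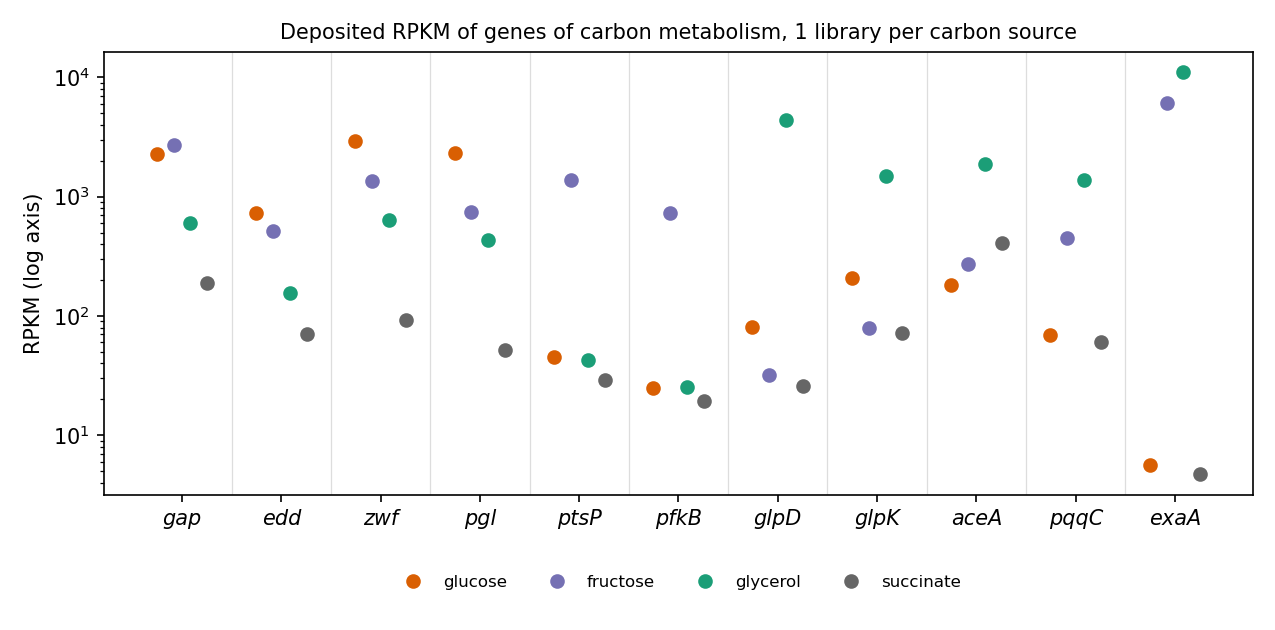
Deposited RPKM (log axis) of 11 genes of carbon metabolism in the 4 libraries, each point being 1 library. The ptsP copy next to cra stood at 1367 RPKM on fructose, glpD at 4370 on glycerol, and zwf next to pgl at 2947 on glucose and 93.0 on succinate.

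The most abundant gene in all 4 libraries was PYW03_RS12240 (2650192 to 2650443), at 29414 RPKM on glucose, 38669 on fructose, 26842 on glycerol and 31370 on succinate. Ribosomal protein gene rpsO was among the first 5 on glucose, fructose and succinate, and acpP, the acyl carrier protein, on glucose and succinate, at 7828 and 11065 RPKM. PYW03_RS10935 was among the first 5 on glucose and fructose, PYW03_RS20035 on glucose and glycerol, PYW03_RS03630 and PYW03_RS05165 on fructose, PYW03_RS15180, exaA and PYW03_RS22165 on glycerol, and ORF_4724712 and PYW03_RS22970 on succinate.

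Of the genes higher than on glucose, 334 were shared by the 741 for fructose and the 422 for glycerol, and 119 of the 207 and 263 lower genes were shared. Independent lists would share 66.8 and 11.6, and unchanged libraries simulated against the same glucose library, for counting error only, shared at most 3 and 2. The simulation held no differences between cultures, so it cannot tell what part of the excess came from the shared glucose culture. The covariance of the log2 ratios across genes, which are not independent replicates, was 0.83 against a simulated 0.0080. Fructose and succinate, each against glucose, shared 68 higher and 68 lower genes, with 24.4 and 6.89 for independent lists and at most 2 and 2 simulated, and a covariance of 0.21 against a simulated 0.0081. Glycerol and succinate shared 29 and 80, with 13.9 and 8.76 for independent lists and at most 4 and 2 simulated, and a covariance of 0.23. In comparisons with no library in common, 340 genes were higher in fructose against glucose and in glycerol against succinate and 66 were lower, with 89.1 and 16.7 for independent lists, and the covariance was 0.62.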

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

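No named gene or list median called at 2-fold changed its direction under any of the alternatives. This was largely fixed in advance and says little about robustness. Pseudocounts and filters cannot turn the ratio of a single gene. The log2 factors of both scalings lay between -0.08 and 0.17 over the libraries, too small to turn a 2-fold difference. The split of genes differing 2-fold turned for glycerol against fructose, from 145 higher and 256 lower to 176 and 161 under median-ratio scaling, and for succinate against glucose, from 154 and 156 to 177 and 144 without the most abundant genes, to 181 and 180 without a filter and to 171 and 167 with reads scaled to depth. The 6 counts of genes differing 2-fold stayed within 1.5 times under 5 of the 7 alternatives. The exceptions were succinate against glucose, with 200 genes in place of 310 at a pseudocount of 10 RPKM, and succinate against fructose, with 695 in place of 1096 at a mean of at least 50 RPKM. Of the library-specific counts, that of fructose was 13 at a pseudocount of 10 RPKM and 15 at a mean of at least 50 RPKM in place of 23, and that of succinate 18 at a pseudocount of 0.1 RPKM in place of 11. A larger pseudocount shrinks the ratios of low genes and a stricter filter leaves fewer genes to count, by construction. Of 114 list medians, 23 moved under median-ratio scaling and 16 under scaling without the most abundant genes, beyond an interval around the median taken from ranked member values. With these scalings 12 and 5 medians changed sign, all under 2-fold, and the cause was not tested. For lists of 3 to 7 measured members that interval ran from the lowest to the highest member. Their medians therefore counted as moved only past all members, and a sign change or a passing of 2-fold within that range did not count. The glyoxylate list has 1 measured member and thus an interval without width. Any change of its value therefore counted as moved, also with the pseudocounts given next. With pseudocounts of 0.1 and 10 RPKM, 8 and 6 list medians moved, and with other filters none did. At a mean of at least 50 RPKM 2 list medians passed 2-fold, and under median-ratio scaling 1 did. Of 721 values of named genes, 215 and 234 moved beyond their counting interval under these scalings, and 6 and 3 fell below 2-fold while 8 and 1 passed it. At a pseudocount of 10 RPKM, 106 moved and 10 fell below 2-fold. No paired analysis was possible because there was 1 library per carbon source, and for the same reason no library could be left out in turn. Genes with few reads had wide intervals, such as 408 to 3835 for the fold of PYW03_RS14050 on fructose.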

Other observations

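All tests below were chosen only after the result was seen, except that of coding length. The runs described first were also found by a rule chosen after the values were seen. Higher in the fructose library than on glucose were 11 runs of at least 4 genes with 71 genes, and 3 runs with 25 genes were lower. On glycerol 9 runs with 61 genes were higher and 5 with 44 genes lower, and on succinate 5 runs with 48 genes were lower. Besides the exaA run, the fructose library held a run of 7 genes from 108809 to 115712 that begins with coxB and ctaD, with a median log2 ratio of 3.70, which on glycerol was a run of 6 genes with a median of 2.38. A run of 5 genes around livM, from 5529377 to 5534471, had a median of 2.73 on fructose, the 5 genes from PYW03_RS21200 to preA 3.17, and benR, benA, benB and benC 2.45 at a median of 28.2 RPKM.

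On glycerol, the genes arcA and arcC of the arginine deiminase pathway lay in a run of 4 genes from 1137538 to 1142426 at a median of 2071 RPKM, against 385 on glucose, 1386 on fructose and 367 on succinate. A run of 4 genes from PYW03_RS16730 to PYW03_RS16750 stood at a median of 217 RPKM on glycerol and at 7.86, 7.64 and 7.30 on glucose, fructose and succinate. The 4 genes from PYW03_RS14170 to PYW03_RS14185 (3087612 to 3091288) were at a median of 548 RPKM on glucose and 285 on fructose, against 17.0 on glycerol and 18.8 on succinate. Single genes also set libraries apart. The azurin gene azu stood at 212 RPKM on glucose, 1738 on fructose, 4129 on glycerol and 1452 on succinate, and aspA at 161, 606, 21.1 and 980.

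The run of 22 genes around exaA was far higher in the fructose and glycerol libraries than on glucose. Reads of the glycerol library carried over into the fructose library are argued against, since the run stood on fructose at a median of 32.4% of its glycerol level (12.0% to 118% over genes), while glpD stood at 0.734% (0.664% to 0.808%) and glpK at 5.25% (4.92% to 5.60%). A swapped label is argued against as well, because ptsP next to cra, pfkB, glpD and glpK were each highest in the library named for their substrate, by at least 7.24-fold. The carbon source, which the design names, stays open as an untested hypothesis. With 1 library each, a difference between single cultures stays open too.

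In the fructose library, far more genes were at least 2-fold higher than lower against glucose. Scaling to total reads as the whole cause is argued against by the median-ratio scaling, after which 62.7% of the genes differing 2-fold were still higher. It could account for part, since that share was 78.2% before. An even background such as DNA, bounded by the 4.16 RPKM under which 5% of genes lay in that library, is argued against for genes with a mean of at least 50 RPKM, since 72.7% of those differing 2-fold were higher. That mean includes the fructose value, so genes low on glucose can pass the filter, and for these the share cannot decide. For genes with a lower mean an even background stays open. Their median gain over glucose was 4.60 RPKM (quartiles -0.46 and 11.3). The median and upper quartile lie above the bound of 4.16 RPKM, so a background within it could account for only part of such gains. Coding length is argued against as the whole cause, since 77.8% of the genes differing 2-fold were higher after the trend with length was removed.

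Differences from glucose were similar in the fructose and glycerol libraries, with a covariance of 0.826 across genes, which are not independent replicates. A glucose library that stands apart on its own is argued against as the whole cause by fructose against glucose and glycerol against succinate, which share no library and had a covariance of 0.616. By construction, the difference between 0.826 and 0.616 equals the covariance of fructose and succinate, each against glucose, of 0.210. As the shared glucose library is 1 culture, how much of that difference the glucose culture brought stays open. The label fields recorded here for the samples named 0 batches, and that count covered those fields alone. Cultures or libraries handled in 2 batches, with fructose and glycerol in 1 of them, therefore cannot be told apart from the carbon source. A biological difference between these carbon sources likewise stays open, as untested.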
